A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

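The deposited table holds counts: whole numbers of 5' ends at 1643818 genome positions and strands, in 8 columns, 1 for each library. Per the labels, 60 µg of total RNA was dephosphorylated with calf intestinal phosphatase and divided into 4 aliquots, which received TAP, Cap-Clip, Decapping Pyrophosphohydrolase or no enzyme. An oligonucleotide with a random barcode of 8 nt was then ligated to the 5' ends. Polyadenylated RNA was selected after ligation, copied from random primers and read for 50 nt. The authors aligned reads with Novoalign, whose version they do not give, to R64 (sacCer3). Whether tags with equal barcodes were collapsed is not stated in the sources used here. The highest count at any position was 57150, and 65536 barcodes are possible. The 8 columns were matched to the groups by their names, and the replicates carry the numbers 1 and 2. Replicates with the same number were taken as aliquots of 1 culture, as the protocol describes.

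Positions were read as 1-based, as the pyrimidine-purine step at -1 and +1 appears at this offset and at no neighbouring one. Gene coordinates came from the R64 annotation, which gave 6002 nuclear protein-coding genes. Each gene had a 5' region, from 200 nt upstream of the start codon to 50 nt into the coding region and ended at an upstream coding region on the same strand, and a gene body, the rest of the coding region. Noncoding genes and the mitochondrial genome, 457 genes, were counted over their span with 200 nt upstream. Paralogs that are nearly identical, such as TDH2 and TDH3, TEF1 and TEF2, HXT6 and HXT7 and pairs of ribosomal protein genes, share reads, so their counts are less certain.

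The tests were chosen before the data were examined. Enzymes were compared over the 6 enzyme-treated libraries with edgeR's quasi-likelihood test, TMM scaling and its filter on low counts, with Benjamini-Hochberg adjusted p under 0.05, 2-sided. CPM values in these comparisons use TMM-scaled library sizes. Each enzyme was compared with no enzyme over all 8 libraries scaled to library totals without TMM, since a control with few capped ends differs in most features. CPM values there and in tag profiles use library totals. Single positions were tested in the same way as regions. Shares of dinucleotides at -1 and +1 were compared with limma on the log2 scale. Shares of tags were compared with a 2-sided exact permutation test, which with 2 libraries against 2 cannot give a p under 0.333. Numbers of detected genes and shared start sites are described without a test. Confidence intervals of shares are Wilson intervals at 95%, and a count of 0 is taken to allow 3 counts. Replicates of 1 group differed by more than counting error, with a chi-square per degree of freedom between 8.32 and 14.0 over 5' regions.

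There were 22 gene lists. Of these, 18 had at least 3 tested members and were tested in 3 enzyme pairs, which makes 54 tests, with camera at its preset correlation of 0.01, then with an estimated correlation, and with fry. Lists of alpha-specific genes, Ty retrotransposons, nuclear ribosomal RNA genes and genes deleted in the strain had too few. The preset correlation gave 26 calls of 54, fry 12 and the estimated correlation 0. With Decapping Pyrophosphohydrolase against either other enzyme, fry called ribosomal proteins, ribosome biogenesis, histones, spliced genes and small nuclear RNAs. It also called mitochondrially encoded genes against TAP, both with Decapping Pyrophosphohydrolase and with Cap-Clip. With a replicate block fry called 0. The names ARG5,6 and SNR7 matched no gene and were left out. The forms SNR7-L and SNR7-S of the U5 RNA share a 5' end and its tags, and the 54 tests count both. After seeing the data the U5 RNA was also counted once, which left 26 calls, and the text gives the list of small nuclear RNAs in that form.

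The text may name, for each comparison, the 10 higher and 10 lower 5' regions with the largest log2 fold change among those called, with a mean of at least 20 CPM and both same-numbered replicate pairs in that direction. It may also name the 10 most abundant genes, the 3 most abundant members of each list, the small nuclear RNAs, the genes deleted in the strain, and 5 higher and 5 lower start sites by the same rule. Named outside this rule, after their values were seen, were the start sites of PFD1 and RPS28B, the small nucleolar RNAs SNR5, SNR70 and SNR128, and clusters of tags outside annotated features. A fold against a group with 0 tags is not printed.

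Pairing of replicates was checked by the correlation, over features, of the difference between replicates 1 and 2 in 1 group with that in another. It lay between 0.0176 and 0.185 over the 8 libraries and between 0.0332 and 0.187 over the 6 enzyme-treated ones. The fits therefore had no replicate term, and a replicate block was an alternative. Other alternatives were scaling to library totals or by TMM, DESeq2, no filter on low counts, 400 nt upstream, positions with at least 2 tags, other samples in the fit, other minimum counts, each position counted once, and leaving out each library in turn. In that last case the remaining library of the group is assumed to vary like the others. Correction for barcode collisions, starts at a pyrimidine-purine step only, and libraries thinned to equal depth were added after seeing the data.

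The fits were tested on simulated data with 200 changed features, in either direction. Between Decapping Pyrophosphohydrolase and TAP 2319 of 4800 real 5' regions were called, so the simulations do not test the scaling under such broad change. For 5' regions a 2-fold change was recovered in 96% of cases between Cap-Clip and TAP, 86.3% between Decapping Pyrophosphohydrolase and TAP and 86.2% between Decapping Pyrophosphohydrolase and Cap-Clip. For features against no enzyme a 4-fold change was recovered in 36.1%, 37.5% and 39.0% of cases for the 3 enzymes, and for start sites in 85.7%, 74.3% and 73.0% for the 3 pairs. Smaller changes were often missed. A 1.5-fold change in 5' regions was recovered in 50%, 38.7% and 39.7% for the 3 pairs, and a 2-fold change at start sites in 33.3%, 27.4% and 31.8%. Against no enzyme a 2-fold change was recovered in at most 4.55%. False calls made up at most 7.59% of calls. The work used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Sequencing reads were not used here.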

Results

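Ligatable 5' ends of polyadenylated RNA were counted in BY4741, a MATa laboratory strain of budding yeast that needs histidine, leucine, uracil and methionine, grown to mid-log phase in rich glucose medium at 30 °C. RNA whose uncapped ends had been dephosphorylated was divided among 4 treatments. TAP (Tobacco Acid Pyrophosphatase), Cap-Clip (an acid pyrophosphatase) and Decapping Pyrophosphohydrolase each open the cap to a ligatable end, and the control received no enzyme. Each group held 2 libraries, replicates 1 and 2. A tag is 1 counted 5' end at 1 position and strand of the R64 (sacCer3) genome build. TAP libraries held 10739034 and 1747139 tags, Cap-Clip libraries 1268757 and 8475181, Decapping Pyrophosphohydrolase libraries 1789278 and 3479399, and no-enzyme libraries 736236 and 80721. Abundances are CPM, counts scaled to 1000000 tags per library. Errors beside means are the SD over n = 2 libraries unless another n is given, and errors beside log2 fold changes are the SE of the fit. Intervals and limits cover counting error only.

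The tags followed the genotype of the strain. LEU2, URA3 and MET17, deleted in BY4741, had 0 tags in all 8 libraries, which in TAP replicate 1 allows up to 0.279 CPM. HIS3, whose deletion lies inside the gene, kept 226 ± 63.0 CPM at its 5' region over the 6 enzyme-treated libraries (SD, n = 6). The a-factor genes MFA1 and MFA2, which encode the mating pheromone of MATa cells, stood at 3087 ± 347 and 3138 ± 826 CPM in these libraries (SD, n = 6). Other genes expressed in MATa cells were AGA2, an agglutinin subunit, at 705 CPM, STE2, the alpha-factor receptor, at 272 CPM, BAR1, which degrades alpha-factor, at 149 CPM, STE6, the a-factor exporter, at 40.8 CPM, and ASG7 at 31.1 CPM. Genes of the opposite mating type were near 0, with MF(ALPHA)1 at 0.571 CPM, MF(ALPHA)2 at 1.07 CPM, STE3 at 0.127 CPM and SAG1 at 1.80 CPM.

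The first comparison asked how far each enzyme directed tags to the 5' ends of genes, where capped ends lie. A 5' region ran from 200 nt upstream of the start codon to 50 nt into the coding region. These regions took 89.9% ± 0.718 of tags with TAP, 89.5% ± 1.04 with Cap-Clip and 88.2% ± 0.286 with Decapping Pyrophosphohydrolase (SD, n = 2 each). The rest of the coding region, here called the gene body, took 5.17% ± 0.341, 5.48% ± 0.803 and 6.72% ± 0.013 of tags. Small nuclear and nucleolar RNA genes took 0.199%, 0.206% and 0.251%, and the mitochondrial genome 0.016%, 0.037% and 0.038%. Nuclear ribosomal RNA genes held at most 2 tags in any library.

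The no-enzyme libraries differed from each other. Without enzyme, replicate 1 placed 13.4% of its tags in 5' regions (Wilson 95% interval 13.3 to 13.4) and 79.1% in gene bodies. No-enzyme replicate 2 placed 71.2% in 5' regions (Wilson 95% interval 70.9 to 71.6) and 23.9% in gene bodies. The mean share in 5' regions was 47.6 percentage points higher with TAP than without enzyme, 47.2 points higher with Cap-Clip and 45.9 points higher with Decapping Pyrophosphohydrolase. Each of these gave p = 0.333 in a 2-sided exact permutation test, the smallest p that 2 libraries against 2 allow. The shares differed by -0.342 points between Cap-Clip and TAP (exact p = 0.667), by -1.64 points between Decapping Pyrophosphohydrolase and TAP (exact p = 0.333) and by -1.29 points between Decapping Pyrophosphohydrolase and Cap-Clip (exact p = 0.333).

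**Figure D1:**
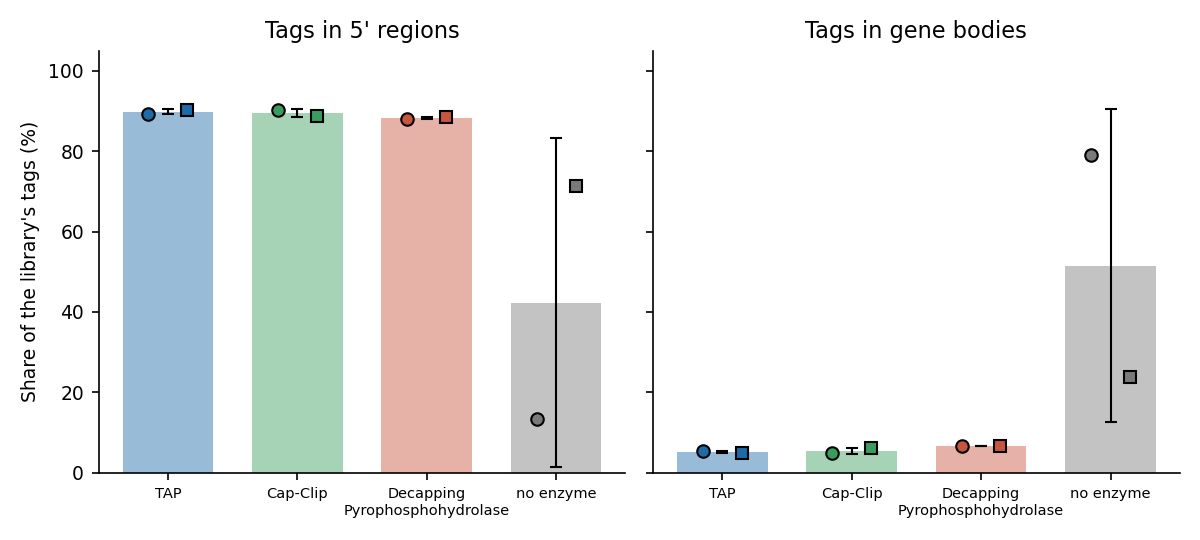
Percent of all tags of each library that lie in 5' regions and in gene bodies, with 2 libraries in each of the 4 groups. The 6 enzyme-treated libraries lie between 88.0% and 90.4% in 5' regions, and the no-enzyme libraries at 13.4% and 71.2%.

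Genes reached at equal depth were counted next. After thinning each library to 80721 tags, 2105 ± 89.1 of 6002 nuclear protein-coding genes had at least 5 tags in the 5' region with TAP and 2040.5 ± 124 with Cap-Clip, whose libraries overlapped (2168 and 2042 against 1953 and 2128). Decapping Pyrophosphohydrolase reached 1564 ± 8.49 genes. The no-enzyme libraries reached 381 genes in replicate 1 and 1286 in replicate 2. At full depth the numbers were 5248 and 4833 for TAP, 4700 and 5196 for Cap-Clip, 4652 and 4917 for Decapping Pyrophosphohydrolase, and 2881 and 1286 without enzyme. The strongest start site of a gene, compared over 3263 regions thinned to 20 tags, lay within 5 nt in 66.8% of regions between the TAP replicates. The mean was 66.9% between TAP and Cap-Clip libraries (66.4% to 67.4% over 4 pairs) and 63.8% between TAP and Decapping Pyrophosphohydrolase libraries (63.3% to 64.8% over 4 pairs). It was 67.3% between the Cap-Clip replicates, 64.3% between the Decapping Pyrophosphohydrolase replicates and 64.8% between Cap-Clip and Decapping Pyrophosphohydrolase (64.3% to 65.3% over 4 pairs).

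Each enzyme was next compared with no enzyme, gene by gene, to separate enzyme-dependent ends from background. With TAP, 3451 of 4715 tested 5' regions rose and 65 fell, whereas 25 of 4314 gene bodies rose and 4153 fell (edgeR, adjusted p under 0.05, log2 relative to library totals). UTP4, a subunit of the small-subunit processome that matures ribosomal RNA, rose by 5.84 ± 0.93 on the log2 scale (72.1 against 0.679 CPM, 1 tag). TPS2, the trehalose-6-phosphate phosphatase, rose by 5.74 ± 0.93 and TIF4631, which encodes the translation initiation factor eIF4G1, by 3.79 ± 0.89. SDD3 and SHQ1 stood at 56.8 ± 7.43 and 56.4 ± 2.04 CPM with TAP and had 0 tags without enzyme. Some 5' regions went the other way. With TAP, MTC7 fell by 4.81 ± 0.56, RPS8B, a protein of the small ribosomal subunit, fell by 4.66 ± 0.54 (5.64 against 160.1 CPM), RPL24A, of the large subunit, fell by 4.27 ± 0.52, and GCN4, the activator of amino acid synthesis genes, by 4.09 ± 0.57 (12.3 ± 0.456 against 209.8 ± 16.4 CPM). With 400 nt upstream RPS8B changed by -0.84 and was not called. The clusters of RPL24A and GCN4 peak 504 and 571 nt upstream, outside both regions, so these falls do not cover those starts. There the means were 576 ± 2.37 and 726 ± 41.3 CPM with TAP, against 269 ± 320 and 331 ± 285 CPM without enzyme.

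Among the gene lists, TAP raised 20 of 27 ribosome biogenesis genes and lowered 0 (19 adjusted over the list alone), 23 of 31 proteasome genes (23 over the list alone), 23 of 40 amino acid synthesis genes (23), 15 of 23 ergosterol genes (14) and 113 of 234 spliced genes (107). ERG11, the lanosterol demethylase, rose by 1.95 ± 0.80 (adjusted p = 0.0264) and PRE2, a catalytic proteasome subunit, by 1.81 ± 0.83 (adjusted p = 0.0436). ERG11 was not called without TAP replicate 1 (1.84) or replicate 2 (1.96), nor was PRE2 (1.73 and 1.84). Respiration and post-diauxic genes had 13 of 16 higher and 1 lower, heat shock genes 11 of 22 higher, translation factors 9 of 24, cell wall genes 7 of 23 and MATa-specific genes 2 of 7. Genes with upstream open reading frames had 5 of 8 higher and 2 lower. Glycolysis genes had 3 of 18 higher and histones 1 of 10, with 0 of either adjusted over the list alone. Of 137 ribosomal protein genes 8 rose and 11 fell (0 and 11 over the list alone). Among the most abundant RNAs, RPL41B, a small protein of the large ribosomal subunit, differed by 0.35 ± 1.26 (adjusted p = 0.792). CCW12, a cell wall mannoprotein, differed by -0.29 ± 1.30 (adjusted p = 0.829), with a positive value of 0.79 under TMM scaling and 0.85 in DESeq2. TDH3, a glyceraldehyde-3-phosphate dehydrogenase, differed by 0.19 ± 1.17.

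Cap-Clip against no enzyme gave 3182 of 4715 5' regions higher and 63 lower, and 24 of 4314 gene bodies higher and 4156 lower. UTP4 rose by 5.50 ± 0.95, WTM2 by 5.33 ± 1.02 and TIF4631 by 3.25 ± 0.88, whereas RPS29B, of the small ribosomal subunit, fell by 4.31 ± 0.54, MTC7 by 4.09 ± 0.54 and GCN4 by 3.77 ± 0.57. The counted regions leave out the clusters of RPS29B and GCN4, which peak 453 and 571 nt upstream. Those clusters held 640.5 ± 87.3 and 606 ± 87.5 CPM with Cap-Clip, against 399 ± 486 and 331 ± 285 CPM without enzyme. Ribosome biogenesis genes had 18 of 27 higher (17 adjusted over the list alone), proteasome genes 22 of 31 (22) and ribosomal protein genes 10 higher and 11 lower of 137 (0 and 11). With Decapping Pyrophosphohydrolase, 1615 of 4715 5' regions rose and 71 fell, and 13 of 4314 gene bodies rose and 4151 fell. IST1, which acts in endosomal sorting, rose by 5.08 ± 1.05 (44.3 CPM, against 0 tags in no-enzyme replicate 1 and 1 tag in replicate 2), OM14, a mitochondrial outer membrane protein, by 4.87 ± 0.95, the septin gene CDC12 by 4.41 ± 0.86 and the proteasome gene RPN9 by 4.35 ± 0.89. Folds of UTP4, TPS2, WTM2, OM14, CDC12 and RPN9 likewise rested on a nearly empty control, of 1 to 3 tags in both no-enzyme libraries together. RPL24B fell by 3.39 ± 0.51 and YJL047C-A by 3.43 ± 0.52. The counted region of RPL24B leaves out its cluster that peaks 433 nt upstream, at 179 ± 22.0 CPM with this enzyme and 126 ± 84.3 CPM without enzyme. GCN4 differed by -0.11 ± 0.51 (adjusted p = 0.849), with positive values of 2.29 under TMM and 1.75 in DESeq2. Ribosome biogenesis genes had 4 of 27 higher (2 adjusted over the list alone), proteasome genes 9 of 31 (2), ergosterol genes 8 of 23 (6) and translation factors 0 of 24 (0). The control includes no-enzyme replicate 2. A mixture given below, fitted to 20096 of its 80721 tags, assigned 91.2% of those to a Decapping Pyrophosphohydrolase profile. The fitted tags lie at selected sites in 5' regions, so this is not a share of the whole library. Counts with this enzyme are therefore not directly comparable with those of TAP and Cap-Clip. Without that library the median log2 fold change of 5' regions was 2.08 with this enzyme, 2.84 with TAP and 2.74 with Cap-Clip. With it the medians were 1.47, 2.21 and 2.09.

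In all, 7694 of 9029 features changed with TAP, 7425 with Cap-Clip and 5850 with Decapping Pyrophosphohydrolase. These counts rested on no-enzyme replicate 1, the deeper control: without it they were 2194, 1851 and 1171, and WTM2 (2.08 with Cap-Clip), MTC7 (-2.32 with TAP, -1.56 with Cap-Clip), RPL24A (-2.63 with TAP), IST1 (1.84), OM14 (1.69), CDC12 (2.74), RPN9 (2.08), RPL24B (-1.08) and YJL047C-A (-1.09) were not called. The 5' regions that rose were then 645, 485 and 43. With TAP they were 2121 without TAP replicate 1, with Cap-Clip 1910 without Cap-Clip replicate 2, and with Decapping Pyrophosphohydrolase 854 without its replicate 1, 754 without its replicate 2 and 3219 without no-enzyme replicate 2. Scaling also mattered, since TMM moved the median of all features by 2.20, 2.23 and 2.55 on the log2 scale. The share of calls that were higher went from 45.2% to 53.2% with TAP, from 43.2% to 53.7% with Cap-Clip and from 27.8% to 58.8% with Decapping Pyrophosphohydrolase, and in DESeq2 it was 63.5%, 65.4% and 72.9%. In DESeq2 the falls of RPL24B (-0.96) and YJL047C-A (-1.02) were not called.

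Cap-Clip was compared with TAP to ask whether the replacement enzyme captures the same ends. The most abundant 5' regions differed by less than their error. Both groups paired a deep and a shallow library, and the 10 fullest positions held a smaller share of tags in the deep one. That share was 3.57% and 7.37% in TAP replicates 1 and 2, and 7.67% and 4.07% in Cap-Clip replicates 1 and 2. The SD of abundant regions may thus include an effect of depth, which was not separated here. RPL41B stood at 13386 ± 6514 CPM with Cap-Clip and 12981 ± 5785 with TAP, CCW12 at 13591 ± 6837 and 10758 ± 5988, and CWP2, a second cell wall mannoprotein, at 11478 ± 1289 and 9333 ± 2170. ADH1, the main fermentative alcohol dehydrogenase, differed by -0.09 ± 0.31 on the log2 scale, FBA1, the glycolytic aldolase, by 0.21 ± 0.31 and TDH3 by 0.13 ± 0.35. The sign for RPL41B turned with the scaling (0.04 ± 0.43 with TMM, -0.07 without). Genes with larger log2 fold changes were HIS3 at 0.47 ± 0.18 (adjusted p = 0.356), PRE2 at 0.45 ± 0.16 (adjusted p = 0.329), TIF4631 at -0.43 ± 0.15 (adjusted p = 0.346) and GCN4 at 0.40 ± 0.23 (adjusted p = 0.585).

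Of 4800 tested 5' regions 0 changed between Cap-Clip and TAP in edgeR, with 486 at an unadjusted p under 0.05 and a lowest adjusted p of 0.166, and DESeq2 gave 0. Without TMM 19 regions were lower with Cap-Clip, and without a filter on low counts 29 of 5642 changed. No protein-coding list had a called member over all regions. Adjusted over the list alone, 1 ribosomal protein gene was higher, 1 ribosome biogenesis gene was higher and 3 were lower, and 1 MATa-specific gene was lower. The median log2 fold change was 0.20 for 137 ribosomal protein genes (adjusted p = 0.554 with an estimated correlation), 0.16 for 10 histone genes (adjusted p = 0.416 with an estimated correlation) and 0.12 for 234 spliced genes (adjusted p = 0.325 with an estimated correlation). The camera test with its preset correlation called these 3 lists higher with Cap-Clip, and also small nucleolar RNAs (median 0.10, turned to -0.0038 without TMM, adjusted p = 0.826 with an estimated correlation) and mitochondrially encoded genes (median 0.52, adjusted p = 0.325 with an estimated correlation).

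The mitochondrial ribosomal RNAs were the genes called between Cap-Clip and TAP. 21S_RRNA rose by 1.68 ± 0.25 (233.7 ± 38.9 against 70.6 ± 11.1 CPM, adjusted p = 0.0215) and 15S_RRNA by 1.67 ± 0.24 (26.0 ± 6.33 against 6.92 CPM, adjusted p = 0.0215). Neither was called without Cap-Clip replicate 1 (1.51 and 1.53) or replicate 2 (1.86 and 2.03), or without TAP replicate 1 (1.89 and 1.99) or replicate 2 (1.56 and 1.64), nor with all 8 libraries in the fit (1.71 and 1.69, adjusted p = 0.808 for each). Adjusted over the list alone, 6 of 16 mitochondrially encoded genes were higher. LSR1, the U2 spliceosomal RNA, differed by 0.08 ± 0.16, and SNR19, the U1 RNA, by 0.07 ± 0.15, both with a negative sign (-0.02 and -0.04) without TMM. SCR1, the RNA of the signal recognition particle, differed by 0.12 ± 0.17 (703 against 646 CPM).

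Decapping Pyrophosphohydrolase was compared with TAP with the same question. Among ribosomal protein genes, RPS8B rose by 5.43 ± 0.18 on the log2 scale (215.8 against 4.61 CPM), RPS29B by 4.64 ± 0.21 (177.6 against 6.85 CPM), RPS29A by 4.25 ± 0.21 (247.4 against 12.2 CPM) and RPS27B by 3.20 ± 0.33 (15939 ± 3148 against 1737 ± 25.9 CPM). Outside this group, GCN4 rose by 4.75 ± 0.20 (266.6 ± 58.7 against 10.2 ± 0.531 CPM), CTS1, the chitinase of cell separation, by 3.92 ± 0.19 (122.8 against 7.97 CPM) and PMA1, the proton pump of the plasma membrane, by 3.91 ± 0.15 (199.7 against 13.4 CPM). The largest falls were in RIA1, a GTPase of 60S ribosome maturation, by 2.26 ± 0.26 (9.44 against 49.4 CPM), IKI3, an Elongator subunit, by 2.00 ± 0.22, MLP1, of the nuclear pore basket, by 2.00 ± 0.23, MDM20, of an N-terminal acetyltransferase, by 1.98 ± 0.22, and DBP7, an RNA helicase of ribosome assembly, by 1.95 ± 0.19 (35.9 against 133.2 CPM). HAC1, the transcription factor of the unfolded protein response, fell by 1.94 ± 0.21 (147.5 ± 52.1 against 578.5 ± 96.9 CPM).

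Several of the largest rises depended on the region counted, because these genes have their strongest start further upstream. With 400 nt upstream in place of 200, CTS1 gave -0.074 (adjusted p = 0.761) and PMA1 0.07, neither called, and RPS8B gave 1.71. GCN4 gave 4.52, RPS29A 4.20 and RPS29B 3.85, but their clusters peak 571, 530 and 453 nt upstream, beyond the wider region. That setting therefore could not show whether these rises depended on the region. Those clusters held 726, 750 and 504 CPM with TAP and 625, 1677 and 943 CPM with Decapping Pyrophosphohydrolase, scaled to library totals. GCN4 had its main cluster of tags 571 nt upstream of the start codon. In the 10 nt that begin 580 nt upstream, the mean was 409.98 CPM with TAP, 332 with Cap-Clip, 345 with Decapping Pyrophosphohydrolase and 156 without enzyme. In the 10 nt that begin 190 nt upstream, it was 1.70 CPM with TAP, 1.65 with Cap-Clip, 129 with Decapping Pyrophosphohydrolase and 40.5 without enzyme. The last value rests on few tags, as the whole 5' region of GCN4 held 163 in no-enzyme replicate 1 and 16 in replicate 2.

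**Figure D2:**
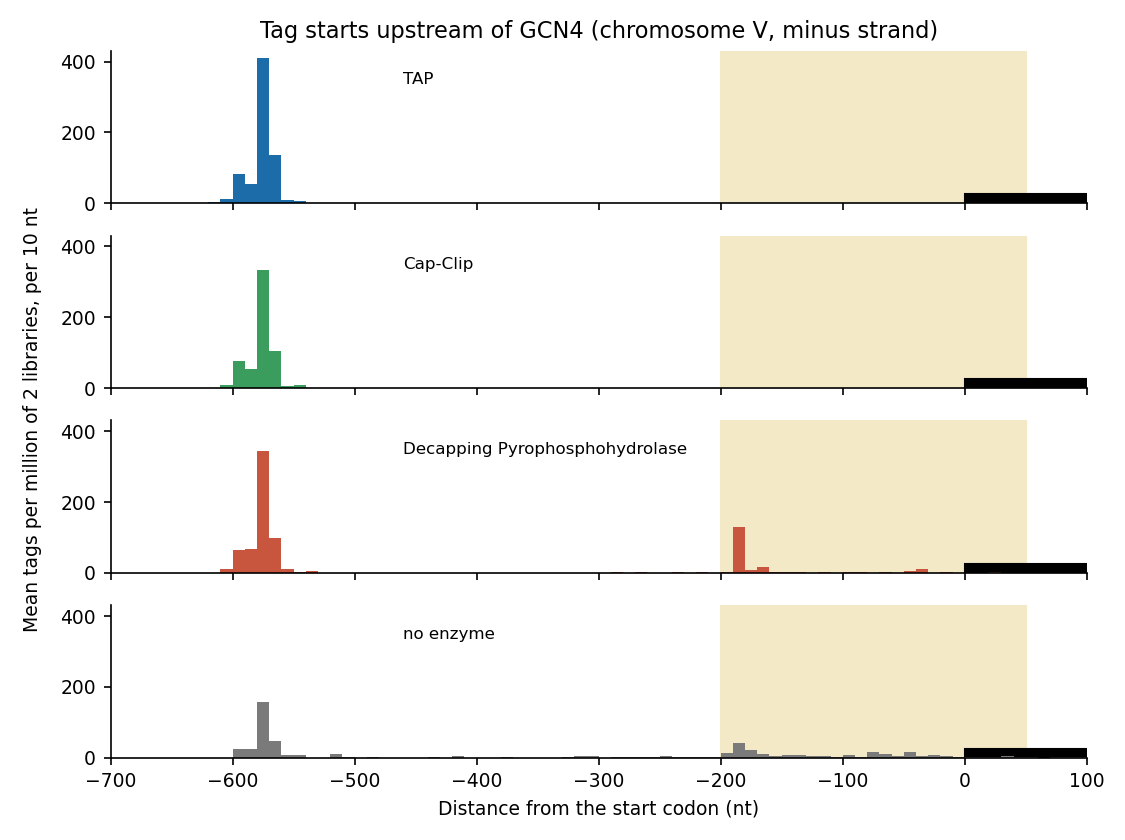
Mean CPM per 10 nt along the GCN4 leader in the 4 groups, against distance from the start codon (n = 2 libraries per group). All enzymes place a peak near -580 nt (409.98 CPM with TAP), and Decapping Pyrophosphohydrolase also places one near -190 nt (129 CPM, against 1.70 with TAP). The no-enzyme mean there was 40.5 CPM, beside 13.7 and 21.2 CPM in the adjacent bins. It rests on few tags, as the whole 5' region held 163 in no-enzyme replicate 1 and 16 in replicate 2.

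Of 4800 regions 1144 rose and 1175 fell with Decapping Pyrophosphohydrolase against TAP. TMM sets this balance: scaled to library totals the median of all regions lay lower by -0.74 and 245 regions were higher and 3059 lower, so the share of calls that were higher went from 49.3% to 7.42%, and it was 59.3% in DESeq2. Without TAP replicate 1, 678 regions were higher and 615 lower, 1293 in all. Ribosomal protein genes had 110 of 137 higher and 0 lower (114 and 0 adjusted over the list alone), with a median of 1.00 (adjusted p = 0.334 with an estimated correlation), and without TMM 53 were higher and 13 lower, with a median of 0.28. Among them RPL41B rose by 1.18 ± 0.44 (adjusted p = 0.0355, not called with a replicate block) and RPS31, which carries ubiquitin, by 1.60 ± 0.33. Cell wall genes had 17 of 23 higher and 1 lower (17 and 1 adjusted over the list alone), with a median of 0.78 (adjusted p = 0.628 with an estimated correlation), and without TMM 3 were higher and 4 lower, with a median of 0.06. Among them were CCW12 at 1.41 ± 0.45 (28551 against 10758 CPM, adjusted p = 0.0173) and CWP2 at 1.14 ± 0.33. Without TAP replicate 1, RPL41B (0.79), CCW12 (0.93) and CWP2 (0.92) were not called, and RPL41B (0.81) was not called without Decapping Pyrophosphohydrolase replicate 1 nor CWP2 (0.91) without replicate 2.

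Glycolysis genes had 10 of 18 higher and 0 lower (14 and 0 adjusted over the list alone), with a median of 0.73 (adjusted p = 0.588 with an estimated correlation), and without TMM 3 were higher and 3 lower, with a median of 0.02. FBA1 rose by 1.57 ± 0.32 (13427 against 4540 CPM) and TDH3 by 1.04 ± 0.35 (adjusted p = 0.0235; 0.63 and not called without TAP replicate 1), whereas ADH1 at 0.68 ± 0.31 did not pass (adjusted p = 0.0807) and was -0.02 without TMM. ADH1 was called without TAP replicate 2 (1.10). Histones had 8 of 10 higher (8 adjusted over the list alone), with a median of 0.78 (adjusted p = 0.325 with an estimated correlation; 2 higher, 1 lower and a median of 0.06 without TMM), and HTB1, a histone H2B gene, rose by 0.73 ± 0.20 (0.60 and not called without TAP replicate 1). Spliced genes had 130 of 234 higher and 24 lower (136 and 24 over the list alone), with a median of 0.64 (adjusted p = 0.325 with an estimated correlation), which turned to 49 higher, 72 lower and a median of -0.077 without TMM. RPL36B, a spliced ribosomal protein gene, rose by 1.87 ± 0.30. Ribosome biogenesis genes had 1 of 27 higher and 12 lower (2 and 12 over the list alone), with a median of -0.36 (-1.08 without TMM, with 0 higher and 24 lower; adjusted p = 0.347 with an estimated correlation), and NOP1, the fibrillarin of yeast, differed by 0.24 ± 0.19 (-0.47 without TMM).

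In the remaining protein-coding lists each positive median turned negative without TMM, and more members were then lower than higher. Amino acid synthesis genes had 15 of 40 higher and 4 lower (median 0.30, without TMM -0.44 with 2 higher and 17 lower), with ILV6, of branched-chain synthesis, at 0.93 ± 0.20. Translation factors had 9 of 24 higher and 5 lower (0.27, without TMM -0.45 with 2 and 13), with TEF1, elongation factor 1A, at 1.21 ± 0.30 (0.94 and not called without TAP replicate 1) and TIF4631 at -1.21 ± 0.16. Heat shock genes had 7 of 22 higher and 1 lower (0.24, without TMM -0.50 with 0 and 12), with the chaperone gene SSB1 at 0.37 ± 0.24 (adjusted p = 0.209). Respiration genes had 6 of 16 higher and 0 lower (0.36, without TMM -0.41 with 1 and 5), with COX8, of cytochrome c oxidase, at 1.22 ± 0.14. MATa-specific genes had 4 of 7 higher and 2 lower (0.51, without TMM -0.21 with 1 and 2), with MFA2 at 1.29 ± 0.25. Ergosterol genes had 5 of 23 higher and 4 lower (0.09, without TMM -0.65 with 2 and 17), with ERG25, the C-4 methyl sterol oxidase, at 1.38 ± 0.15 (643.5 against 248.2 CPM). Proteasome genes had 10 of 31 higher and 8 lower (0.03, without TMM -0.69 with 2 and 20), with RPN8 at 0.93 ± 0.15. Adjusted over the list alone these counts were the same except for 5 higher MATa-specific genes and 2 lower ergosterol genes. Genes with upstream open reading frames had 1 of 7 higher, GCN4, and 3 lower (1 and 3 over the list alone), with a median of -0.46 and a mean of 0.19, and without TMM 1 was higher and 6 lower, with a median of -1.22. The camera test with its preset correlation called 0 of the lists in this paragraph. HIS3 rose by 1.42 ± 0.18.

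**Figure D3:**
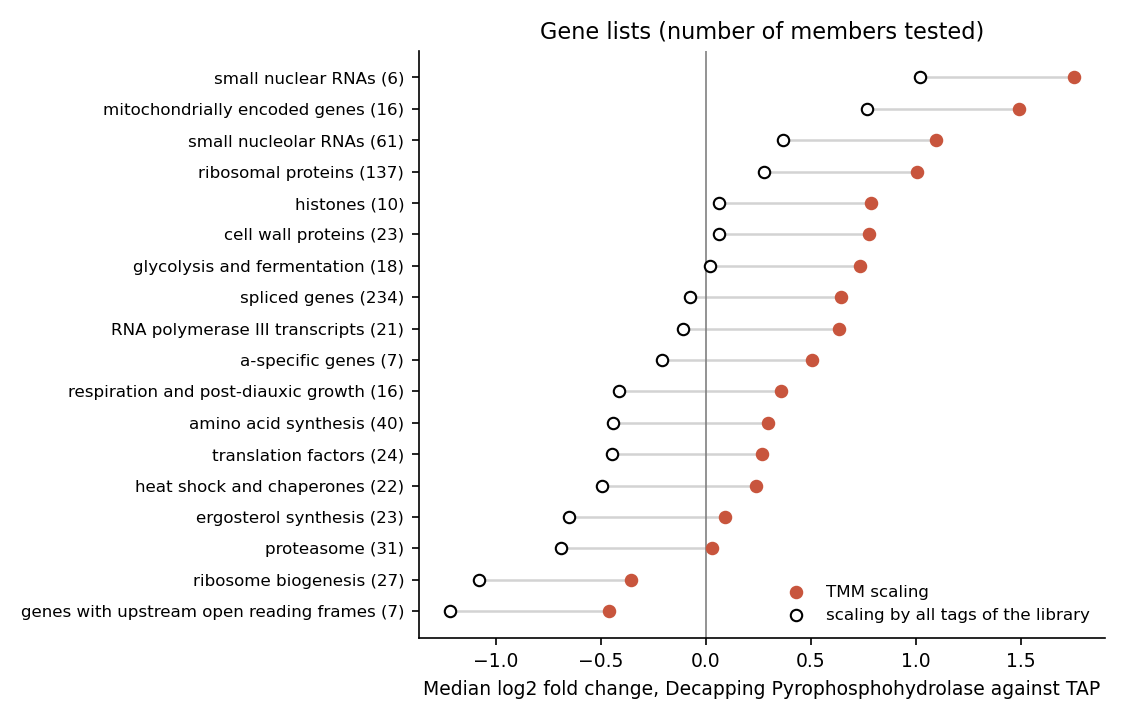
Median log2 fold change of each gene list for Decapping Pyrophosphohydrolase against TAP, n = 2 libraries per group. With TMM, ribosomal proteins lie at 1.00 and ribosome biogenesis at -0.36 for Decapping Pyrophosphohydrolase against TAP, and without TMM they lie at 0.28 and -1.08, while lists such as spliced genes turn from 0.64 to -0.077. Small nuclear RNAs are drawn with the forms SNR7-L and SNR7-S as 2 members.

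RNAs made outside the protein-coding genes were also compared between Decapping Pyrophosphohydrolase and TAP. Small nucleolar RNAs had 42 of 61 higher and 0 lower (46 and 0 adjusted over the list alone), with a median of 1.10 (0.37 without TMM with 21 higher and 2 lower, adjusted p = 0.537 with an estimated correlation). SNR33 rose by 1.88 ± 0.23 and SNR190 by 2.14 ± 0.27. Small nuclear RNAs, which carry a trimethylguanosine cap, had 4 of 5 higher and 1 lower (4 and 1 over the list alone), with a median of 0.98 (adjusted p = 0.343 with an estimated correlation), and without TMM 2 were higher and 1 lower, with a median of 0.26. The U5 RNA is counted once in these values. SNR14, the U4 RNA, rose by 3.32 ± 0.32 (19.5 against 1.56 CPM), the U5 RNA, whose forms SNR7-L and SNR7-S share this 5' end, by 2.52 ± 0.26, TLC1, the telomerase RNA, by 0.98 ± 0.15 (0.26 without TMM, not called) and SNR19 by 0.75 ± 0.15 (0.05 without TMM, not called). LSR1 fell by 0.93 ± 0.17 (122.3 against 230.9 CPM). Mitochondrially encoded genes had 15 of 16 higher (15 over the list alone), with a median of 1.49 (0.76 without TMM with 11 higher, adjusted p = 0.325 with an estimated correlation), including 21S_RRNA at 1.55 ± 0.25 and 15S_RRNA at 2.77 ± 0.24. RNA polymerase III transcripts had 10 of 21 higher (10 over the list alone, 6 of 23 without TAP replicate 1 and 19 of 39 without TAP replicate 2), with a median of 0.63 that turned to -0.11 without TMM with 7 higher and 7 lower (adjusted p = 0.554 with an estimated correlation). SCR1, of this list, differed by -0.00 ± 0.17 (644.1 against 646 CPM).

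The bases at the start of the tag were compared to ask whether an enzyme prefers certain ends. Here -1 is the genome base before the tag and +1 its first base. A T at +1 began 5.67% ± 0.562 of tags in 5' regions with Decapping Pyrophosphohydrolase, against 0.931% ± 0.099 with TAP and 0.945% ± 0.086 with Cap-Clip. A C began 2.32% with Decapping Pyrophosphohydrolase against 1.29% and 1.23%. Starts with a pyrimidine at -1 and a purine at +1, the usual form of a yeast start site, made up 82.3% ± 2.11, 90.3% ± 1.10 and 90.3% ± 0.903 of these tags. Among 48 tests of 16 dinucleotides in 3 enzyme pairs, limma called 18, of which 16 were higher with Decapping Pyrophosphohydrolase and 2 lower, and called none between Cap-Clip and TAP. Against TAP the dinucleotide TT rose by 3.21 ± 0.14 on the log2 scale, GT by 2.78, AT by 2.62 and CT by 1.71. When each position was counted once, whatever its number of tags, 0 of the 48 were called.

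**Figure D4:**
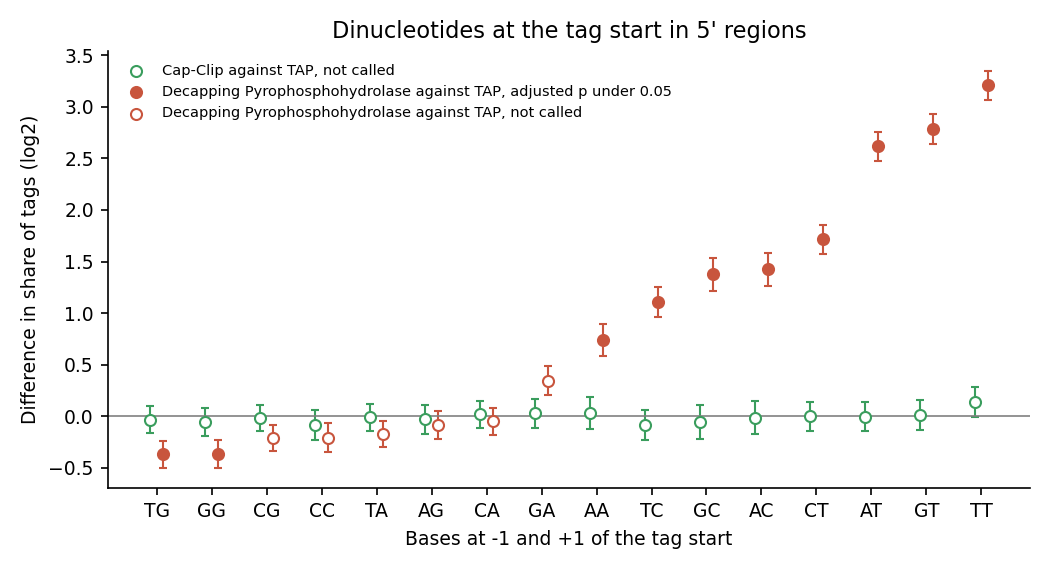
Log2 difference in the share of tags in 5' regions for each dinucleotide at -1 and +1, for Cap-Clip and Decapping Pyrophosphohydrolase each against TAP, with SE (n = 2 libraries per group). The values for TT, GT, AT and CT lie between 1.71 and 3.21 for Decapping Pyrophosphohydrolase against TAP, and all values for Cap-Clip against TAP lie near 0.

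Single start sites were tested at 26891 positions of the 5' regions. Between Decapping Pyrophosphohydrolase and TAP, 6104 rose and 4053 fell. Of 1296 sites with T at +1, 1160 rose (89.5%), with a median log2 fold change of 6.02, whereas 3637 of 18180 sites with A rose, 873 of 6633 with G and 434 of 782 with C. PGK1, the glycolytic phosphoglycerate kinase, had 97.3 ± 16.8 CPM at chromosome III position 137724, 22 nt upstream of its start codon, and 0 tags there with TAP. ARF1, a GTPase of vesicle budding, had 66.7 ± 26.0 CPM at chromosome IV position 116250, VMA3, of the vacuolar proton pump, 48.8 ± 6.25 CPM at chromosome V position 100717, PMP3 70.2 ± 3.08 CPM at chromosome IV position 1013674, and RPS27B 68.4 ± 18.6 CPM at chromosome VIII position 148727, each with 0 tags with TAP. Sites that fell include those of RPA135, an RNA polymerase I subunit, by 3.13 ± 0.31 at chromosome XVI position 581253, RPS12 by 3.09 ± 0.28 (6.64 against 55.5 CPM) at chromosome XV position 1028650, TIF4631 by 2.87 ± 0.27 at chromosome VII position 824019, IKI3 by 2.73 at chromosome XII position 892885, and HAC1 by 2.60 ± 0.27 (90.2 against 556 CPM) at chromosome VI position 75113. Without TAP replicate 1 5291 sites were called and without Decapping Pyrophosphohydrolase replicate 2 6180, against 10157 in all. Without TMM 3451 were higher and 10088 lower, and DESeq2 gave 4026 and 1197.

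Between Cap-Clip and TAP, 2 of the 26891 sites were called, both lower with Cap-Clip and named here after their values were seen. They lay at PFD1, a subunit of the prefoldin chaperone (chromosome X position 88730, -1.94 ± 0.32, 3.92 against 18.5 CPM, adjusted p = 0.0109), and at RPS28B, of the small ribosomal subunit (chromosome XII position 673120, -1.62 ± 0.25, 7.42 against 23.9 CPM, adjusted p = 0.00685). At an unadjusted p under 0.05 there were 1528 sites, DESeq2 called 0, and a replicate block called 70, 19 higher and 51 lower. Without Cap-Clip replicate 1, Cap-Clip replicate 2 or TAP replicate 1, 0 sites were called, and PFD1 gave -1.84, -2.52 and -2.25 and RPS28B -1.56, -1.81 and -1.60.

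Decapping Pyrophosphohydrolase was last compared with Cap-Clip. RPS8B rose by 4.39 ± 0.17 on the log2 scale (215.8 against 10.1 CPM), RPS29B by 4.36 ± 0.22, GCN4 by 4.35 ± 0.20 (266.6 against 14.1 CPM), PMA1 by 4.01 ± 0.16, CTS1 by 3.42 ± 0.19 and RPS26A, of the small ribosomal subunit, by 2.51 ± 0.15 (319.8 against 57.4 CPM). With 400 nt upstream PMA1 gave -0.16 (adjusted p = 0.515) and CTS1 -0.22 (adjusted p = 0.349). RPS8B, RPS29B and GCN4 also have clusters that peak outside the counted regions, 397, 453 and 571 nt upstream. Scaled to library totals, these held 75.7, 943 and 625 CPM with Decapping Pyrophosphohydrolase and 125, 640.5 and 606 CPM with Cap-Clip. HAC1 fell by 1.90 ± 0.21 (147.5 against 561.8 CPM), VBA4, of a family of vacuolar amino acid transporters, by 1.83 ± 0.17, RIA1 by 1.78 ± 0.28, FOB1, which binds the replication fork barrier of ribosomal DNA, by 1.63 ± 0.21, DBP7 by 1.62 ± 0.19 and SPB1, a methyltransferase of ribosome assembly, by 1.59 ± 0.21. RPL41B at 1.14 ± 0.44 (adjusted p = 0.0511) and CCW12 at 1.07 ± 0.44 (adjusted p = 0.0691) did not pass, but without Cap-Clip replicate 1 both were called (1.74 and 1.70), as was RPL41B without Decapping Pyrophosphohydrolase replicate 2 (1.43) and CCW12 without replicate 1 (1.21). FBA1 rose by 1.36 ± 0.32 (adjusted p = 0.00402; 1.12 and not called without Cap-Clip replicate 2), COX8 by 1.00 ± 0.14 and ERG25 by 1.09 ± 0.15.

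Of 4800 regions 955 rose and 850 fell with Decapping Pyrophosphohydrolase against Cap-Clip, 1805 in all. Without TMM the median of all regions lay lower by -0.63 and 214 were higher and 2666 lower, so the share of calls that were higher went from 52.9% to 7.43%. It was 62.7% in DESeq2. Without Cap-Clip replicate 2, 533 were higher and 403 lower, 936 in all. Ribosomal protein genes had 96 of 137 higher and 0 lower (100 and 1 adjusted over the list alone; median 0.83, without TMM 0.22 with 44 higher and 12 lower; adjusted p = 0.334 with an estimated correlation). Cell wall genes had 16 of 23 higher (18 over the list alone; median 0.76, without TMM 0.14 with 3 and 1; adjusted p = 0.588 with an estimated correlation), glycolysis genes 10 of 18 (14 over the list alone; 0.74, without TMM 0.15 with 3 and 1; adjusted p = 0.562 with an estimated correlation) and histones 6 of 10 (6 over the list alone; 0.65, without TMM 0.05 with 2 and 1; adjusted p = 0.325 with an estimated correlation). Ribosome biogenesis genes had 1 of 27 higher and 11 lower (1 and 11 over the list alone; median -0.29, without TMM -0.90 with 0 and 23; adjusted p = 0.334 with an estimated correlation).

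Lists whose positive median turned negative without TMM in this pair were spliced genes, with 111 of 234 higher and 21 lower (115 and 23 over the list alone; 0.46 and -0.14, with 40 higher and 71 lower without TMM; adjusted p = 0.325 with an estimated correlation), and amino acid synthesis, with 13 of 40 higher and 1 lower (13 and 1 over the list alone; 0.29 and -0.33, with 2 and 14; adjusted p = 0.775 with an estimated correlation). The others were translation factors with 9 higher and 3 lower (11 and 5 over the list alone; 0.35 and -0.26, with 1 and 9), respiration with 5 higher (5 over the list alone; 0.36 and -0.27, with 1 and 5), heat shock with 4 higher and 1 lower (4 and 1 over the list alone; 0.31 and -0.31, with 1 and 8), MATa-specific genes with 3 higher and 1 lower (4 and 1 over the list alone; 0.51 and -0.11, with 1 and 3) and ergosterol with 4 higher and 3 lower (4 and 2 over the list alone; 0.09 and -0.53, with 1 and 12). Proteasome genes had 8 higher and 5 lower (8 and 5 over the list alone), with a median of -0.08 and a mean of 0.04, and without TMM 1 was higher and 19 lower, with a median of -0.70. Genes with upstream open reading frames had 1 higher and 3 lower (1 and 4 over the list alone), with a median of -0.56 and a mean of 0.17, and without TMM 1 was higher and 5 lower, with a median of -1.21.

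Outside the protein-coding genes, small nuclear RNAs, with the U5 RNA counted once, had 4 of 5 higher with Decapping Pyrophosphohydrolase than with Cap-Clip and 1 lower (median 0.85, 0.24 without TMM with 2 higher and 1 lower; adjusted p = 0.343 with an estimated correlation). SNR14 rose by 3.12 ± 0.34 and LSR1 fell by 1.01 ± 0.17. Small nucleolar RNAs had 37 of 61 higher (40 over the list alone, 18 of 60 without Cap-Clip replicate 2; median 0.98, without TMM 0.37 with 21 and 5, adjusted p = 0.537 with an estimated correlation) and mitochondrially encoded genes 10 of 16 (10 over the list alone, 4 of 18 without Cap-Clip replicate 2; 1.08, without TMM 0.43 with 7 and 1, adjusted p = 0.416 with an estimated correlation), although 21S_RRNA differed by -0.13 ± 0.24. That gene was called lower (-0.75) without Decapping Pyrophosphohydrolase replicate 2. RNA polymerase III transcripts had 9 of 21 higher and 1 lower (9 and 1 over the list alone, 5 and 1 of 24 without Cap-Clip replicate 2, 19 and 0 of 38 without Cap-Clip replicate 1; median 0.45, without TMM -0.19 with 9 and 6; adjusted p = 0.628 with an estimated correlation).

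At single sites 5484 rose and 3086 fell between Decapping Pyrophosphohydrolase and Cap-Clip, 8570 in all. ACB1, the acyl-CoA-binding protein, had 45.3 ± 8.93 CPM at chromosome VII position 560020 and 0 tags there with Cap-Clip. RPP2B, of the ribosomal stalk, rose by 9.59 ± 0.42 (157 against 0.430 CPM) at chromosome IV position 1239428 and PMA1 by 9.25 (123 CPM) at chromosome VII position 482672. RPS12 fell by 2.91 at chromosome XV position 1028656, SNU13, a protein of the U4/U6.U5 particle and of box C/D particles, by 2.80 at chromosome V position 101827, and HAC1 by 2.50 at chromosome VI position 75113. Without Cap-Clip replicate 2 4098 sites were called and without Decapping Pyrophosphohydrolase replicate 2 5255, and DESeq2 called 3417 higher and 806 lower.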

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

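The search for tags outside the regions of protein-coding genes, with its minimum of 100 CPM and its distance of over 400 nt, was chosen after the data were seen. It singled out 7 clusters of tags outside 5' regions and gene bodies, with the peak over 400 nt upstream of the next start codon on the strand, whose level in each of the 6 enzyme-treated libraries lay above that of the higher no-enzyme library. Clusters nearer to a start codon were left aside. Values are the mean CPM over these 6 libraries. The cluster with its peak at chromosome VII position 438438, minus strand, held 589 ± 21.3 CPM, 504 nt upstream of the start codon of RPL24A, against 495.5 CPM in the higher no-enzyme library. A cluster at chromosome IV position 216102, plus strand, held 396 ± 33.8 CPM, 427 nt upstream of ARF2, which encodes a GTPase of vesicle budding. Another at chromosome IV position 652718, plus strand, held 299.5 ± 59.3 CPM, 889 nt upstream of BMH2, a 14-3-3 protein gene, against 99.1 CPM in the higher no-enzyme library. At chromosome XIV position 500962, plus strand, 276.7 ± 49.8 CPM lay 553 nt upstream of SUN4, a cell wall protein gene. Chromosome XIV position 546649, plus strand, held 115.5 ± 12.9 CPM, 464 nt upstream of YNL042W-B. Chromosome XII position 818362, minus strand, held 146.3 ± 44.2 CPM, against 69.3 CPM in the higher no-enzyme library. The cluster at chromosome V position 424695, plus strand, held 130 ± 26.5 CPM and ended 1 nt before SNR4, a small nucleolar RNA gene with which these tags were counted in the comparisons of noncoding genes, so they are not outside the data used. No explanation of these clusters was tested.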

How the results depend on the processing

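Added after seeing the data were correction for barcode collisions, starts at a pyrimidine-purine step only, libraries thinned to equal depth and the U5 RNA counted once. For the genes and sites named in the text, 1488 values were computed under alternatives: 1340 kept direction and side of the threshold, 81 lost their call, 23 gained one and 41 without a call changed sign. In 3 more cases, all with 400 nt upstream, the call was lost and the sign turned: CTS1 against TAP (-0.074) and, with Decapping Pyrophosphohydrolase against Cap-Clip, PMA1 (-0.16) and CTS1 (-0.22), since the wider region takes in the clusters 231 nt upstream of CTS1 and 236 nt upstream of PMA1. For all other differences given here the cause was not tested.

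Counts of 5' regions between Cap-Clip and TAP went from 0 to 19 without TMM, 29 without a filter and 1 with 400 nt upstream. For Decapping Pyrophosphohydrolase against Cap-Clip they went from 1805 to 2880 without TMM and 1188 in DESeq2. DESeq2 called 0 start sites between Cap-Clip and TAP, 5223 between Decapping Pyrophosphohydrolase and TAP and 4223 between Decapping Pyrophosphohydrolase and Cap-Clip. Dinucleotides called went from 18 to 0 with each position counted once. Gene lists called went from 26 to 0 with an estimated correlation and 12 with fry. The replicate block gave 70 start sites between Cap-Clip and TAP in place of 2, with RPL41B not called between Decapping Pyrophosphohydrolase and TAP (1.11) and PRE2 not called between TAP and no enzyme (1.83), and under the replicate block no other named call was lost, and the total of gene lists called by fry went from 12 to 0 but no other total moved by over 1.5 times. Counts within totals also moved under the replicate block: the 2 lower dinucleotides became 0, lower translation factors against Cap-Clip went from 3 to 5, higher ribosome biogenesis genes against TAP from 1 to 2, and lower respiration genes against TAP and lower ribosomal protein genes against Cap-Clip each from 0 to 1.

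Shares of tags in 5' regions were 92.2% with TAP, 91.7% with Cap-Clip and 90.2% with Decapping Pyrophosphohydrolase for 400 nt upstream, and 42.5%, 43.9% and 44.3% with each position counted once. Main start sites shared with at least 50 tags per region were 77.5% for Cap-Clip and TAP, 74.95% for Decapping Pyrophosphohydrolase and TAP and 75.1% for Decapping Pyrophosphohydrolase and Cap-Clip. With at least 20 tags per region, main start sites at exactly the same position were 57.95%, 54.7% and 56.0% for these pairs. At equal depth, genes with at least 1 tag were 4222 for TAP, 4124.5 for Cap-Clip, 3668 for Decapping Pyrophosphohydrolase and 3023.5 without enzyme, and with at least 20 tags 662, 628, 499 and 236.

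Leaving out 1 library gave 1293 (without TAP replicate 1) to 2570 regions for Decapping Pyrophosphohydrolase against TAP, 936 (without Cap-Clip replicate 2) to 2146 against Cap-Clip and 0 to 0 for Cap-Clip against TAP. Against no enzyme it gave 2194 to 9494 features with TAP, 1851 to 9352 with Cap-Clip and 1171 to 8487 with Decapping Pyrophosphohydrolase, the lowest each without no-enzyme replicate 1. Start sites ranged from 0 to 2 for Cap-Clip against TAP, 5291 (without TAP replicate 1) to 12199 for Decapping Pyrophosphohydrolase against TAP and 4098 (without Cap-Clip replicate 2) to 10373 against Cap-Clip, and without Decapping Pyrophosphohydrolase replicate 2 they were 6180 and 5255. Genes detected without enzyme ranged from 381 to 1286. In this setting the remaining library is assumed to vary like the other groups. No-enzyme replicate 2 held 80721 tags, and of 20096 of them, at sites in 5' regions with at least 10 tags over the enzyme-treated libraries and below 1000 in each library, 91.2% were assigned to a Decapping Pyrophosphohydrolase profile.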

Other observations

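Chosen after the results were seen were the tests of cleavage at a sequence motif, of capped ends, of the sources of no-enzyme replicate 2 and of motif density, and the description of small nucleolar RNAs and upstream clusters. Some clusters of tags lay upstream of the 5' regions counted here. RPL32, a ribosomal protein gene, had a cluster with its peak 365 nt upstream of the start codon, at 4077 ± 1360 CPM over the 6 enzyme-treated libraries (SD, n = 6). The higher no-enzyme library held 5550 CPM, above the lowest enzyme-treated one. RPS29A had one 530 nt upstream at 1112 CPM and RPS25B one 468 nt upstream at 1094 CPM. GCN4, with its leader of upstream open reading frames, had one 571 nt upstream at 652 ± 103 CPM. In these 3 as well the higher no-enzyme library (941.5, 991 and 532.7 CPM) exceeded the lowest enzyme-treated one (682, 815 and 508.6 CPM). CTS1 had one 231 nt upstream, at 981 CPM with TAP, 1005 with Cap-Clip and 483 with Decapping Pyrophosphohydrolase, and PMA1 one 236 nt upstream, at 527, 575 and 199 CPM, against 520 and 223 CPM in the higher no-enzyme library, above the lowest enzyme-treated one in both.

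Small nucleolar RNAs, counted over their span, were compared with no enzyme. Of 60 tested, 35 fell and 7 rose with TAP, 37 and 9 with Cap-Clip, and 35 and 14 with Decapping Pyrophosphohydrolase, with medians of -2.56 with TAP (-0.42 with TMM) and -2.17 with Decapping Pyrophosphohydrolase, which turned to 0.25 with TMM. These counts rested on no-enzyme replicate 1: without it 7 fell and 0 rose with each enzyme, with medians of -0.035 with TAP, -0.11 with Cap-Clip and a turn to 0.36 with Decapping Pyrophosphohydrolase. Without no-enzyme replicate 2, 17, 19 and 19 of 65 rose, and 4 did without either TAP replicate, 5 and 4 without Cap-Clip replicates 1 and 2, and 4 without Decapping Pyrophosphohydrolase replicate 1. SNR190 fell by 5.56 with TAP (89.8 CPM, against 7699 and 756 without enzyme) and SNR128, the U14 RNA, by 4.95 ± 1.08 (71.1 CPM, against 4044 and 322). SNR70 fell by 5.23 ± 1.09, which rested on no-enzyme replicate 1 (-0.33 and not called without it). LSR1 rose by 2.18 ± 0.70 (277.9 CPM, against 61.1 and 61.9, not called without TAP replicate 1 at 2.15), and SNR5, which guides pseudouridine formation, by 3.26 ± 0.70 (87.7 CPM, against 6.79 and 24.8, not called without no-enzyme replicate 1 at 1.82). Mitochondrially encoded genes had 18 of 19 lower with TAP (median -4.05, -1.97 with TMM), and RNA polymerase III transcripts 15 of 24 (median -1.76, which turned to 0.53 with TMM). Without no-enzyme replicate 1 these were 6 of 19 (median -2.10) and 1 of 29 (turned to a median of 0.69).

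Start sites at RN|WTT, a purine at -2, any base at -1 and then A or T followed by TT from +1, were often higher with Decapping Pyrophosphohydrolase. Of 1049 tested sites with this motif 642 were higher than with TAP (median log2 fold change 6.41 of these), 66 were lower (-1.29) and 341 were not called (-0.039). Off the motif 5462 were higher (median 1.39), 3987 lower and 16393 not called. Only 10.5% of the higher sites carried the motif, and T at +1 alone had 1160 of 1296 higher (median 6.02 over all of them). Among the higher motif sites are those of PGK1, PMP3, RPS27B, ARF1 and VMA3. The sites of ACB1 and PMA1, raised against Cap-Clip, lack the motif. In gene bodies the motif held 14.7% ± 0.860 of tags with this enzyme, 2.50% ± 0.046 with TAP and 3.02% ± 0.059 with Cap-Clip, against 3.03% of all positions. With the motif moved 1 nt upstream, its libraries held 8.88% and 8.24%, against 2.16% and 2.19% with TAP. Moved 1 nt downstream, the shares were 4.94% and 4.69% against 1.64% and 1.81%. At the motif itself the lowest Decapping Pyrophosphohydrolase share was 4.614 times the highest of the other enzymes. Cleavage by an endonuclease with the preference of RNase E may thus account for these sites, though the excess was not confined to that exact position. Depth argues otherwise at 6.232, the ratio between Decapping Pyrophosphohydrolase replicate 1 and TAP replicate 2 of nearly the same depth, and fragments present before the RNA was divided argue otherwise at 0.1995, the share in no-enzyme replicate 1 over that in Decapping Pyrophosphohydrolase replicate 1. Capped ends that TAP leaves closed stay open for these sites, because their share upstream of the main start was 0.7232 of that among sites not called, between the bounds set for either outcome, and they also stay open for the other 5462 higher sites, where the share was 1.065 of that among lower sites. The groups were aliquots of the same RNA, so no biological explanation was tested.

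No-enzyme replicate 2 held 57508 tags in 5' regions, of which the background of no-enzyme replicate 1, scaled by gene-body tags, would give 5.68%. In a mixture of the other libraries' profiles, fitted to the 20096 of these tags that lie at sites with at least 10 tags over the 6 enzyme-treated libraries and below 1000 in each library, Decapping Pyrophosphohydrolase made up 91.2% (89.1 to 93.5), and 94.9% of the part not taken by no-enzyme replicate 1, which is consistent with carry-over from a Decapping Pyrophosphohydrolase library or of that enzyme. TAP and Cap-Clip together made up the remaining 5.101% of that part. This is the complement of the 94.9%, so it is the same fit, not a second test, that argues against carry-over from them. Phosphates left at cap sites by incomplete dephosphorylation are argued against by 25.95, the ratio of no-enzyme replicate 2 to the higher TAP library in tags at the sites Decapping Pyrophosphohydrolase raised by over 3 on the log2 scale, per tag at sites not called. Background also scores high on this measure, with 30.7 tags per 100 in no-enzyme replicate 1 and 11.9 in replicate 2. Scaled by gene-body tags, however, replicate 1 would give only 238 of the 3258 tags of replicate 2 at the raised sites. Whether library or enzyme was carried over, and a difference between the cultures, stay open.

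Genes with long coding regions had lower 5' counts with Decapping Pyrophosphohydrolase than with TAP: the median log2 fold change was 0.42 at a median coding length of 612 nt, 0.03 at 1206 nt and -0.61 at 2235 nt. Across 4800 regions, which are not independent replicates, Spearman's rho with coding length was -0.6033. Cleavage between the cap and the poly(A) tail of long RNAs is a candidate explanation. The rho restates the trend, however, and cannot tell cleavage from other causes tied to length. Cap-Clip against TAP had a rho of -0.565 over smaller changes (0.12 for short and -0.20 for long genes), by library -0.540 and -0.489 with Cap-Clip replicate 2 but -0.271 and -0.279 with replicate 1, whereas replicates of 1 enzyme gave -0.109, 0.169 and -0.0148. Depth and barcode collisions are argued against by -0.5941 between 2 libraries of nearly the same depth, and abundance by a partial correlation of -0.5225 given the mean level. Cleavage at RN|WTT inside the coding region cannot be told apart from other sites of cleavage, as the partial correlation with motif density was -0.05745, between the bounds set for either outcome.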
